A study of Homo sapiens with 6 samples.

How the data were processed

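Mature microRNAs were measured on 1-colour microarrays in Huh7, a cell line derived from a human hepatocellular carcinoma. Per the labels, 3 samples were left without metformin and 3 received 10 mM metformin, a biguanide drug for diabetes, with both kept for 72 h. Total RNA was labelled with the dye Hy5 using a commercial microRNA labelling kit, per the labels' protocols. One deposited value table holds all 6 arrays. Its values are linear intensities that the authors had already processed. This is inferred from the values, which all lie above 0 and have nearly equal medians in the 6 columns. The scanner, background correction, scaling method and rule for empty cells are not given in the sources used here. No scanner output was used here, so no probe could be flagged as above or below background, and depth has no meaning beyond the number of arrays, which limits the precision.

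The table holds 1212 probes, against 985 stated in the series' design text. The reason for the difference is not given in the sources used here. Of the 1212 rows, 1206 carry 1 miRBase mature-microRNA accession and 6 carry several. The gene table used here holds 0 rows with such an accession, so the files do not pair probes with microRNA names and no name is printed. The 24 microRNA lists (families, genomic clusters, liver cancer and cell type markers) fixed before the data were examined, and the set tests planned on them (camera with a preset correlation of 0.01, with an estimated correlation, and fry), could not be run for the same reason. The naming rule fixed at that time allows 2 probe identifiers per direction where no name is paired, taken by smallest unadjusted p when too few probes pass the threshold.

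Intensities were converted to log2 with no pseudocount. A total of 224 cells are null, affecting 174 probes. The 1038 probes with a value on all 6 arrays were tested, which leaves out mostly dim probes. Metformin was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and plain eBayes, two-sided), over all 6 arrays without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The same model gave 95% intervals for each difference, which are not adjusted for the number of probes. Values per array were compared by exact permutation tests, in which 3 against 3 arrays cannot give a two-sided p below 0.1. No column of the table was left out. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

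The procedure was tested on simulated data. In 50 runs, 200 of the 1038 probes were changed by known folds. Each probe's spread was the moderated one of the limma fit, and noise was drawn independently for each probe and array. The mean false discovery share was 3.87% and the 95% intervals covered the true difference for 95.1% of probes. Such noise meets the assumptions of the test, so these 2 values check the procedure and not the real arrays. With nothing changed, the simulation gave a mean of 52.7 probes at an unadjusted p under 0.05, against 28 on the real arrays. The recovered shares below may therefore not hold for the real arrays. Among the 260 probes brightest on average, the test recovered 7.54% of changes of 1.5-fold, 54.1% of changes of 2-fold and 99.8% of changes of 4-fold. Among the other probes it recovered 8.87%, 44.3% and 96.6%, respectively. These shares hold for that many changed probes and would be lower with fewer.

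Alternatives fixed before the data were examined were quantile normalization, centring on the array median or on its 75th percentile, restriction to the 519 or the 260 brightest probes, probes with at least 2 values per group, log2(value + 1), eBayes with trend and robust settings, an unmoderated equal-variance test, the replicate number as a block, and leaving out each array. Chosen after seeing the data were a model with the first 3 and the last 3 arrays deposited as a block, a repeat without probes whose value on control replicate 1 has more than 1 decimal, the counts of probes at an unadjusted p under 0.05 and of intervals that exclude a 2-fold change, and the comparison of the 104 brightest probes. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.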

Results

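The series asked which microRNAs change in abundance when liver cancer cells are exposed to metformin. Huh7 cells without metformin (control, 3 arrays) were compared with Huh7 cells kept in 10 mM metformin for 72 h (3 arrays). Tumour tissue that the series' design text also mentions was not analysed here.

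Each array gave between 1099 and 1209 probes with a value. Median intensities ranged from 22.8 on metformin replicate 2 to 24.1 on metformin replicate 3. The lowest value on any array was 4.70 and the highest 19416. A few probes carried most of the signal, since the 10 brightest probes of each array held between 50.2% and 52.9% of its summed intensity. The brightest probe had a mean intensity of 15013, taken as the geometric mean of the 6 arrays, whereas only 260 of the 1038 probes tested had a mean of 32.5 or higher. Log2 intensities correlated across all tested probes with r between 0.87 and 0.93 for the 15 pairs of arrays. Spearman rank correlations of the same pairs were lower, from 0.57 (control replicates 2 and 3) to 0.79 (control replicates 1 and 3). Over the 260 brightest probes r lay between 0.97 and 0.99. These correlations are across probes, which are not independent replicates. Arrays of the same group were no closer to each other (mean r = 0.904 over 6 pairs) than arrays of different groups (mean r = 0.908 over 9 pairs). Pairs within the first 3 or within the last 3 arrays deposited had a mean r of 0.913 over 6 pairs. Pairs across these sets had 0.902 over 9 pairs. The comparison by group was not balanced for this order.

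No microRNA probe passed the threshold for a change with metformin. Of 1038 probes tested, 0 were higher and 0 were lower at an adjusted p under 0.05 by limma, and the lowest adjusted p was 0.107. At an unadjusted p under 0.05 there were 28 probes, 17 higher and 11 lower with metformin, where 51.9 would be expected if nothing had changed. That count was 44 without control replicate 2, 50 with the deposit order of the arrays as a block and 18 with trend and robust settings. Every setting fitted fell short of the expected share, and the highest share was 4.82% of probes, with the deposit-order block. The size of the shortfall therefore depends on the model, and the shortfall is no evidence that nothing changed. Of the 28 probes, 20 were among the 260 dimmest and 0 among the 260 brightest. The 3 metformin values lay wholly above or wholly below the 3 control values for 79 probes (7.61%), where chance gives 10%. Only 8 probes differed by more than 2-fold in their group means, and 0 of these were among the 260 brightest. None of the 18 alternative settings called a probe.

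The brightest probes were measured tightly enough to bound the change in intensity. Background correction is not known, so this need not bound the change in microRNA abundance. Signal differs between probes for reasons other than abundance, so brightness here does not rank the microRNAs themselves. Among the 260 brightest probes (mean intensity 32.5 or higher), the differences ran from -0.39 to 0.54 on the log2 scale, and the median SD within a group was 0.24. The 95% interval excluded a 2-fold change in either direction for 229 of them (88.1%). The typical half-width of that unadjusted interval was 0.57, or 1.49-fold. After adjustment the test was less sensitive than this, since on simulated data it recovered 7.54% of 1.5-fold and 54.1% of 2-fold changes among these probes. The 260 dimmest probes (mean intensity 18.0 or lower) had a median within-group SD of 0.64. Their interval excluded a 2-fold change for only 22 probes (8.46%). In all, the interval excluded a 2-fold change in intensity for 570 of the 1038 probes. Of these, 121 were among the 259 probes with mean intensity 18.1 to 22.5, and 198 among the 259 with 22.5 to 32.5. Whether a shared background held such values together was not tested.

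**Figure D1:**
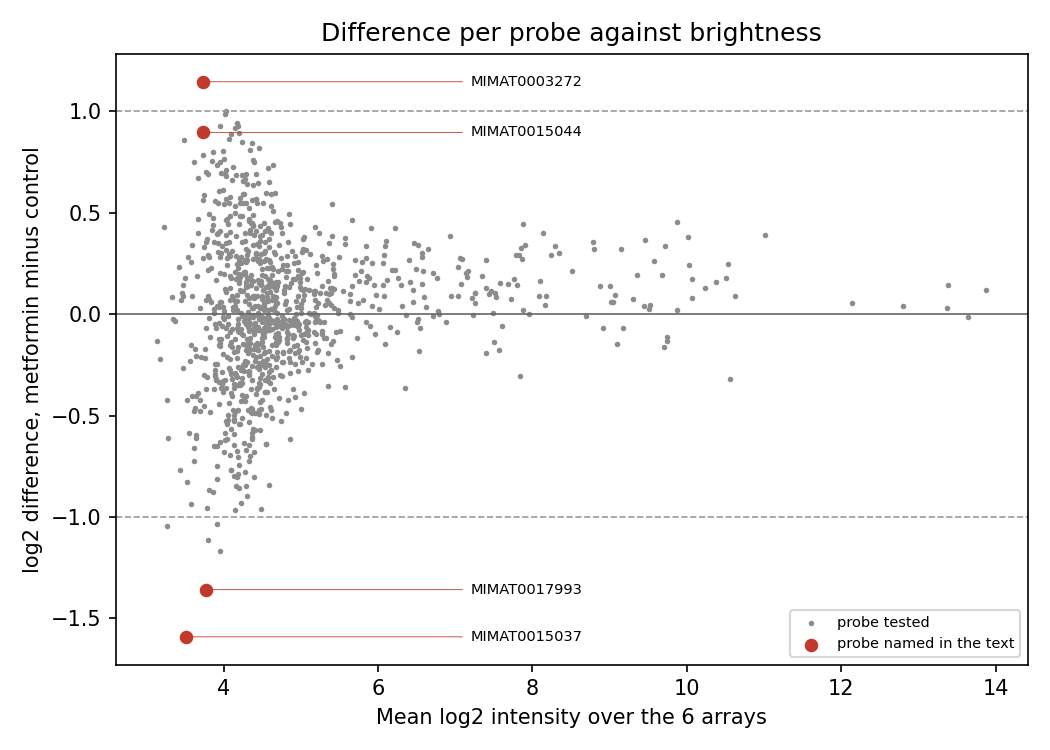
Each point is 1 of the 1038 probes tested, with its mean log2 intensity over the 6 arrays on the x axis and its log2 difference, metformin minus control, on the y axis; dashed lines mark a 2-fold difference. The spread narrows with brightness, the 4 probes named in the text (red) lie at the dim end, and 0 of the 260 brightest probes reach 2-fold.

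The probes with the smallest p in each direction were all dim, and none passed the threshold after adjustment. The files give them only by their mature-microRNA accession. The probe MIMAT0015037 had intensities of 22.6, 17.3 and 20.1 in control (SD 2.65, n = 3) and a mean of 6.60 ± 0.20 (SD, n = 3) with metformin. Its log2 difference was -1.59 (SE 0.22, 95% interval -2.10 to -1.08), with a limma adjusted p = 0.107. Its metformin values of 6.80, 6.60 and 6.40 lay close to the lowest values on those arrays (5.80, 6.20 and 4.70). Its mean brightness was at the 1.83 percentile of the probes tested. The adjusted p of this probe ranged from 0.089 to 0.989 over its 16 alternatives. The next, MIMAT0017993, stood at 22.2 ± 5.08 in control and 8.90 ± 3.36 with metformin (SD, n = 3), a log2 difference of -1.36 (SE 0.33). In the other direction, MIMAT0003272 measured 9.36 ± 3.13 in control and 19.9 ± 2.53 with metformin (SD, n = 3), a difference of 1.15 (SE 0.31). Its value on control replicate 1, 5.87, is the lowest on that array, and without that array the difference was 0.84. MIMAT0015044 measured 9.90 ± 2.10 in control and 18.3 ± 2.31 with metformin (SD, n = 3), a difference of 0.90 (SE 0.25). These last 3 probes each had a limma adjusted p = 0.991. All 4 lay within the dimmest 5.97% of the probes tested.

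Whole-array levels of the processed values differed between the groups by less than the spread between arrays. The scaling method is not known. If it set the arrays to a common level, these comparisons could not show a shift of all microRNAs together. The median log2 intensity of an array was 4.62 ± 0.02 (SD, n = 3) in control and 4.60 ± 0.06 (SD, n = 3) with metformin (two-sided exact permutation p = 0.6). The median of the 1038 differences was 0.03, but its sign turned without control replicate 2 (-0.0091) and without metformin replicate 3 (-0.0019). It also turned with the deposit order as a block (-0.00074). After quantile normalization it was -0.0056, but that method removes a whole-array shift by construction, so this sign says nothing. Summed intensity was 128153 ± 11150 in control and 135528 ± 11350 with metformin (SD, n = 3; two-sided exact permutation p = 0.5).

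The brightest probes leaned towards higher values with metformin, by an amount within the spread between arrays. Of the 104 brightest probes (mean intensity 95.2 or higher), 87 had a higher mean with metformin, and their median log2 difference was 0.12. The level of these probes on each array, taken as the median deviation from the probe means, was -0.05 ± 0.15 (SD, n = 3) in control and 0.06 ± 0.14 (SD, n = 3) with metformin. The two-sided exact permutation p was 0.5, and 0.75 after Benjamini-Hochberg adjustment over the 5 array-level measures compared. Only 1 of the 3 metformin arrays lay above every control array. Without metformin replicate 2 the median difference was 0.04, without control replicate 2 it was 0.05, without control replicate 3 it was 0.19, and without metformin replicate 1 it was 0.20. After quantile normalization, which removes such a shift by construction, it was 0.

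**Figure D2:**
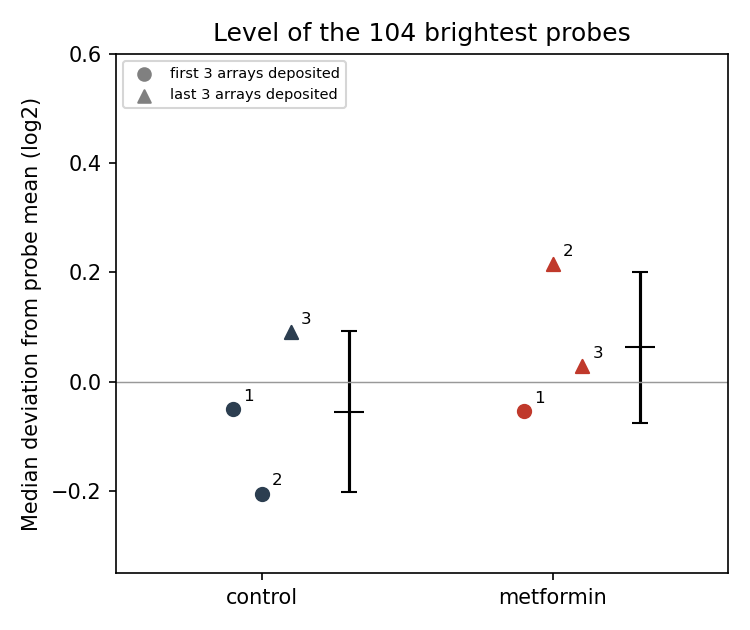
Each symbol is 1 array, numbered by replicate, with the median deviation of the 104 brightest probes from their means (log2) on the y axis; circles are the first 3 arrays deposited, triangles the last 3, and bars show the group mean ± SD (n = 3). The control arrays span -0.20 to 0.09 and the metformin arrays -0.05 to 0.22, so the groups overlap.

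The 6 arrays were also compared by their place in the deposit. The first 3 (control replicates 1 and 2, metformin replicate 1) gave 32 probes past the threshold against the last 3 (metformin replicates 2 and 3, control replicate 3) among the 260 brightest, 3 among the 519 brighter probes and 0 among all 1038. The 32 became 12 without metformin replicate 3, 15 without metformin replicate 1 or without metformin replicate 2, 20 without control replicate 2, 24 without control replicate 3, 34 without control replicate 1, 20 after quantile normalization and 16 with treatment in the model. The labels name no batch. With that split as a block, metformin against control again gave 0 probes past the threshold by limma, and 50 at an unadjusted p under 0.05. Within the first 3 arrays alone 0 probes passed and 39 had an unadjusted p under 0.05. Within the last 3 the numbers were 0 and 49. Each of these fits has a single array in 1 group, which was assumed to vary like the other group, so its count of 0 says nothing about stability. For the 104 brightest probes the median difference was 0.06 with the block, 0.08 within the first 3 arrays and 0.01 within the last 3.

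Null cells did not differ between the groups by more than the spread between arrays. Control arrays had 27.3 ± 8.50 null cells and metformin arrays 47.3 ± 58.0 (SD, n = 3; two-sided exact permutation p = 0.9). Metformin replicate 2 had 113 and metformin replicate 3 had 3. No probe was null on all arrays of 1 group and measured on all arrays of the other (0 in either direction). Probes null on metformin replicate 2 were dim on the other arrays, with a median intensity of 14.2 against 22.7 for the rest.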

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

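All 18 alternative settings gave 0 probes past the threshold in total and in each direction, as in the reported fit. The replicate numbers shared by control and metformin samples were not treated as pairs, since no label says that they pair samples. Correlations of the deviations from the group means did not settle the question. For numbers 1, 2 and 3, r was 0.01, -0.27 and -0.02 over all probes, and 0.24, -0.26 and 0.44 over the 260 brightest. With the replicate block 0 probes passed and 24 had an unadjusted p under 0.05, against 28 without it. That unadjusted count was 10 of the 519 brighter probes, 1 of the 260 brightest, 18 with trend and robust settings and 50 with the deposit-order block, and it ranged from 23 to 44 when 1 array was left out (44 without control replicate 2). The filtered sets hold fewer probes, but the share with an unadjusted p under 0.05 also fell, from 2.70% of all probes to 1.93% and 0.38%. The fall was already present in the fit of all probes. There the 28 comprised 20 of the 260 dimmest probes, 6 of the next 259, 2 of the following 259 and 0 of the 260 brightest. The cause was not tested. After quantile normalization the count among the 260 brightest was 7. When the 260 brightest probes were fitted alone, the interval excluded a 2-fold change for 252 of them, against 229 in the fit of all probes. Over all probes that count, 570, ranged from 401 (without metformin replicate 3) to 544 when 1 array was left out, and was 461 with the unmoderated test, 513 with the replicate block and 616 with log2(value + 1). The whole-array median difference of 0.03 turned to -0.0056 after quantile normalization and to -0.00074 with the deposit-order block. It ranged from -0.0091 to 0.066 when 1 array was left out, with the sign turned without control replicate 2 (-0.0091) and without metformin replicate 3 (-0.0019). The median difference of the 104 brightest probes was 0 after quantile normalization. The 4 named probes stayed short of the threshold in all 63 refits that included them. They also kept their sign, but this was largely fixed in advance. They were chosen by smallest p, and their control and metformin values do not overlap, so leaving out an array cannot turn it. The list tests and their alternatives were not run, because the probes carry no microRNA names. Precision is limited by 3 arrays per group. It was lower for dim probes, whose values lie nearer the lowest values on the array, but the cause was not tested.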

Other observations

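The comparisons of metformin with control over all probes and over the 260 brightest were planned for adjusted calls. The counts at an unadjusted p and the tests on accession numbers, on the deposit-order split, on the 104 brightest probes and on the format of control replicate 1 were chosen after seeing the data, although the prediction for leaving out metformin replicate 2 from the deposit-order split was written before its result was seen.

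Probes with early accession numbers were brighter, which compares different probes and so does not rank the abundance of their microRNAs. miRBase numbers mature microRNAs in the order of their registration. Of 189 tested probes numbered under 1000, 53 (28.0%) were among the 104 brightest, against 51 of 849 (6.01%) with later numbers (Fisher's exact test, p = 5.7e-16, across probes, which are not independent). Their median intensities were 31.99 and 21.8. The level of the early-numbered probes was -0.03 ± 0.14 in control and 0.06 ± 0.09 with metformin (SD, n = 3; two-sided exact permutation p = 0.4).

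The 6 arrays can be split into 3 against 3 in 10 ways. Over all 1038 probes the treatment split gave 0 calls and the highest other split also gave 0, so all 10 gave as many. A count of 0 fixes that outcome in advance, so it decides nothing, and 10 splits are too few for a share under 0.05. Over the 260 brightest probes the treatment split gave 0 calls and 1 at an unadjusted p under 0.05, or 0 and 7 after quantile normalization. The split of the first 3 arrays deposited against the last 3 gave 32 calls and 67 at an unadjusted p under 0.05 (20 and 61 after quantile normalization), where 13 would be expected by chance. The highest other split gave 0 calls, and again 10 splits are too few for a share under 0.05 (1 of 10 gave as many). Over all 1038 probes this split gave 0 calls and 108 at an unadjusted p under 0.05, against 104 for control replicates 1 and 3 with metformin replicate 2. The 32 calls hint at a structure of the samples, but it was not shown. Of the 32 probes, 31 were higher on the last 3 arrays, with a median absolute log2 difference of 0.65.

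Quantile normalization did not remove all calls of that split, since 20 were left, 13 of them among the 32. With treatment in the model 16 calls were left, 14 of them among the 32. The limit for this test was set after the data were seen and was only just met. It therefore does not decide whether the unequal number of metformin arrays on the 2 sides accounts for the split. Metformin replicate 2 alone was argued against by the rule written beforehand, because 59 probes had an unadjusted p under 0.05 without that array. Chance would give 13. However, calls fell from 32 to 15, and probes are not independent. A large part played by that array is therefore not excluded. Leaving out each array in turn gave between 12 and 34 calls, with 12 without metformin replicate 3, 15 without metformin replicate 1 and 20 without control replicate 2. Also open are chance and a difference in culture, labelling, hybridization or scanning between the 2 sets of arrays, which may lie behind the split. No label records one, and no biological explanation was tested.

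The tilt of the 104 brightest probes towards metformin remains undecided. Its median log2 difference over the probes was 0.12. The difference between the mean array levels of the groups was 0.118, with a standard error between arrays of 0.117. A treatment effect could not be excluded or shown, with a one-sided exact permutation p of 0.25. It may reflect the deposit-order split, because 2 of the last 3 arrays are metformin arrays, and with that split as a block the difference was 0.060. It may also rest on metformin replicate 2, without which it was 0.040, although leaving out control replicate 2 lowered it to 0.055 as well. Each of these values lies within 1 standard error of the array levels from 0.12. That error does not measure the change from leaving out an array or adding a block. None of the explanations can be told apart for these probes.

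Control replicate 1 was written in a mixed format. Its column holds 201 values with more than 1 decimal and 975 with at most 1, while the other 5 arrays hold 0 of the former. The 201 values deviated from the mean of control replicates 2 and 3 by a median of -0.01 on the log2 scale (SD 0.57), against 0.03 (SD 0.55) for the others. Without these probes, 0 of 864 passed the threshold and 23 had an unadjusted p under 0.05.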
